A study of Mus musculus with 8 samples.

How the data were processed

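Gene expression was measured in lungs of C57/Bl6 mice at postnatal day 6, the time at which the air spaces are being subdivided by secondary septa. The tips of secondary alveolar septa were cut from frozen sections by laser capture, a microscope-guided method that lifts chosen areas from a section, and 10000 tips were collected. RNA of pooled whole lung was prepared in parallel. The whole experiment was carried out with tissue from different litters in experiment 1 and again in experiment 2, and each amplified RNA was hybridised to 2 Affymetrix arrays at different times. The series thus held 8 arrays of 4 RNA samples, 2 RNA samples per group. Groups were taken from the sample titles, because the description of the tip samples names whole lung tissue. Per the labels' protocols, RNA was extracted with a PicoPure kit, amplified with a RiboAmp kit and labelled with biotin. An amplification step is written in the labels of all tip arrays and of array 1 of the lung RNA of experiment 1, while the series' design text states that the RNAs of both tissues were amplified in parallel.

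The deposited values are intensities, a signal per probe set on a linear scale, made by the authors with MAS5 per the submitters' processing notes, which give no version. From the values, each array had been scaled by the authors to a common level: the mean after leaving out 2% of the probe sets at each end lay between 1501 and 1501.2 on every lung array and between 1500.6 and 1500.7 on every tip array. Detection calls were not used here. The table held 12488 probe sets, of which 66 were control probe sets. In the probe annotation, 10855 probe sets carried 1 gene symbol, 396 carried several and 1237 were not named. Of the symbols, 10839 were updated by gene ID to those of the GRCm38.p6 RefSeq table. Probe sets with several symbols or none were tested but not named. No genome build is given in the sources used here, so no coordinates are printed.

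From these values, each array was scaled to the common trimmed mean of 1500.9, an offset of 150.09 (10% of that mean) was added, and log2 was taken, so that differences of dim probe sets are understated. Control probe sets were left out, as were probe sets whose mean log2 value over all arrays lay under the 40th percentile, which left 7453. The arrays of an RNA were averaged first, since they are technical repeats, and the RNA samples were the replicates. Tips and lung were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), and an adjusted p (Benjamini-Hochberg) under 0.05 was the threshold. The fit had 2 residual degrees of freedom and 7.05 prior degrees of freedom. The p-values rest on the spread between RNA samples of different litters, which also holds that between arrays. They rest as well on a prior spread pooled over probe sets. The number of RNA samples, and so of arrays, limits the precision: the median standard error of a log2 difference was 0.40. The 31 gene lists were fixed before the data were examined and tested with limma's camera, with a preset correlation of 0.01 between genes, on the brightest probe set of each gene. Lists with fewer than 3 measured genes would not have been tested, and all 31 were. Background was the 95th percentile of 19 control probe sets for bacterial and yeast transcripts on each array. Where every array of a group lay under background, the fold is given as a lower limit: the brighter group's mean was set against, per array, the higher of the background and the measured signal. Standard deviations of signals are over the 2 RNA samples of a group.

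Named genes followed a rule fixed before the data were examined. They were the 12 in each direction with the largest difference among those past the threshold and in the same direction in all 4 array pairs, up to 4 members of each list by smallest p, and Lgals1, Eln, Acta2, Pdgfra, Sftpc, Scgb1a1 and Pecam1 whatever their values. Further genes are given in the text only as called members of a list. Probe set names that end in f_at, s_at, r_at or similar mark probes that other transcripts can share, and genes with near-identical copies, such as those of ribosomal proteins and haemoglobins, are uncertain for the same reason.

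The experiment number marks shared processing of tips and lung in the design text, so it pairs the RNA samples. Across probe sets, the deviations of tips and lung from their group means correlated at 0.0452 in experiment 1, and with 2 RNA samples per group experiment 2 gives the same value. With the experiment as a block, 2452 probe sets passed in place of 2106, and 2098 passed in both fits. The procedure was tested on 20 simulated data sets of 7453 probe sets with 200 changed ones, drawn with the spread of the real RNA samples in each group and with independent errors. For the comparison of tips with lung it recovered 0.97% of the changes of 1 on the log2 scale, 36.0% of those of 2 and 77.8% of those of 3. Of the calls, 3.47% were false, against 11.9% with the experiment as a block. These rates hold for 200 changed probe sets, while the real fit called 2106, and the adjusted p depends on that share. The list test was simulated with independent errors, 1 spread for both groups and no other changed genes. A list of 15 genes shifted by 1 on the log2 scale was then recovered in 100% of the simulated sets, and 0 unshifted lists were called. In the real data 1677 of 5642 genes were called and the ribosomal list had an estimated correlation of 0.27, so these rates do not carry over to them.

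Alternatives fixed before the data were examined were quantile normalization, centring on the median, cyclic loess, no rescaling, other offsets, no filter and a filter at the 60th percentile, the block, all 8 arrays with the RNA sample as a random block, either array alone, no intensity trend, leaving out each RNA sample, and other list tests. A common floor at the highest background level of any array was added after the data were seen, and a lower floor at the second highest level after that. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.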

Results

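The tips of secondary alveolar septa, captured by laser from lungs of mice at postnatal day 6, were compared with whole lung of the same age on 8 oligonucleotide arrays. There were 2 RNA samples per group, from experiments with different litters, and 2 arrays per RNA sample. After the authors' scaling, the median signal lay between 501 and 572 on the lung arrays and between 787 and 924 on the tip arrays. The 95th percentile lay between 9009 and 9243 on the lung arrays and between 6218 and 6845 on the tip arrays. The median signal of the bacterial and yeast control probe sets, which stand for background, ranged from 66.9 to 97.3 on lung arrays and from 121 to 332 on tip arrays. All p-values of single genes below are adjusted p from limma over the 7453 probe sets tested, and all differences are log2 differences of tips minus lung with their standard error, n = 2 RNA samples per group.

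To find genes enriched in secondary septa, the purpose stated by the title of the series, tips were set against whole lung. Lgals1, which encodes the beta-galactoside-binding lectin galectin-1, rose from a signal of 2457 ± 432 in lung to 12730 ± 3615 in tips (SD, n = 2), a log2 difference of 2.29 ± 0.32 (limma adjusted p = 0.00217). The difference was 2.75 in experiment 1 and 1.83 in experiment 2, and all 4 array pairs gave the same direction. Tips also carried more signal for the contractile genes Csrp1, Tagln and Actg2, for the matrix genes Tnc, Hspg2 and Lamb2, for the surfactant gene Sftpc and for several ribosomal proteins. Contractile and matrix genes did not all rise: Mylk fell by 2.50 and Col5a2 by 2.02. Acta2 gave 0.09 (limma adjusted p = 0.890). Tips carried less for the homeobox gene Meox2, the replication clamp Pcna and the lysosomal protease gene Ctss. The Hedgehog receptor gene Ptch1 fell by 2.74 at its brightest probe set, while another gave 1.23 (limma adjusted p = 0.0521). In all, 2106 probe sets passed the threshold, 1084 higher and 1022 lower in tips, and without the lung RNA of experiment 1 or of experiment 2 the total was 349 or 556.

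**Figure D1:**
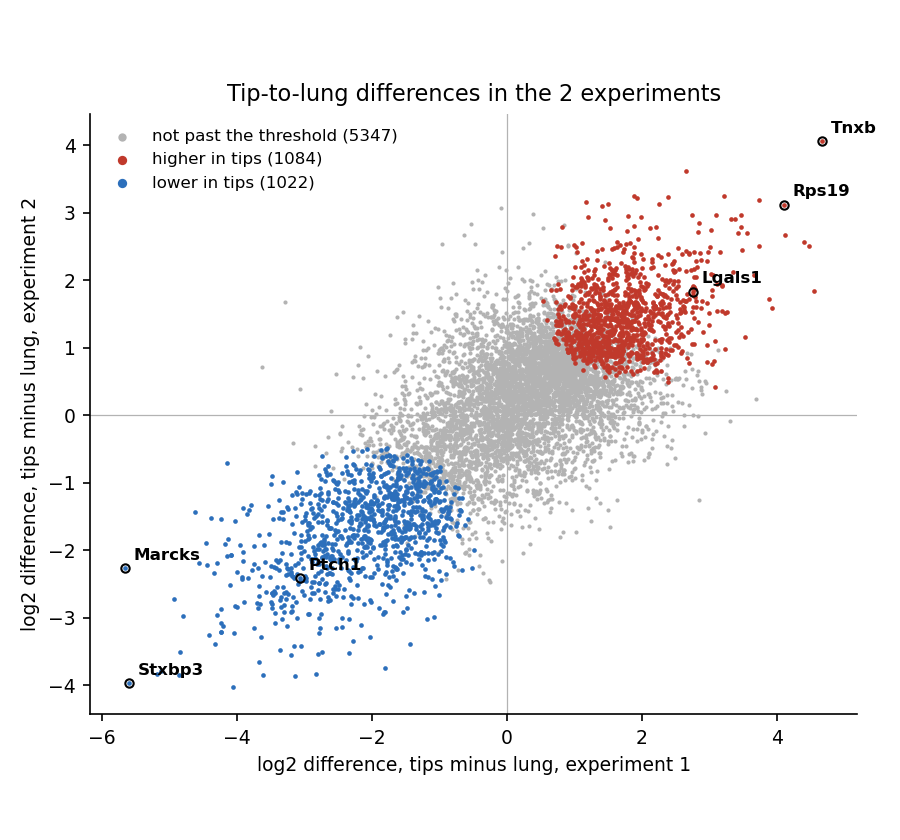
Each point is a probe set, with its log2 difference of tips minus lung in experiment 1 on the horizontal axis and in experiment 2 on the vertical axis. The 1084 probe sets higher in tips are red, the 1022 lower in tips are blue and the rest are grey. Every called probe set lies on the same side of 0 in both experiments, which its selection on the same data largely fixes.

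Among the 12 genes with the largest increases in tips were Tnxb, which encodes the matrix glycoprotein tenascin-X, the ribosomal protein genes Rps19 and Rpl19, and Mdk, which encodes the heparin-binding growth factor midkine. Tnxb was under background on all 4 lung arrays and at least 10.5-fold higher in tips, taken against the background of each lung array (adjusted p = 0.000941). The same limit was 7.14-fold for P3h3, 4.41-fold for Mob2 and 3.09-fold for the casein kinase gene Csnk1e. Rps19 rose by 3.61 ± 0.33, Mdk by 3.24 ± 0.37 and Csrp1, a LIM domain protein of smooth muscle, by 3.13 ± 0.37. The others were Ppp4c, Tspan31, Septin4 and Phc2, at 3.49, 3.48, 3.19 and 3.13. Ppp4c, Mdk and Phc2 were above background on only 1 of the 4 lung arrays, and Tspan31 and Csrp1 on 2. With a common floor, all values under 1244, the highest background level of any array, set to it, Tspan31, Mob2 and Csnk1e did not pass, at 2.07, 0.91 and 0.47. Array 2 of the tip RNA of experiment 1 alone sets that level, and with a lower floor at the next highest, 792, Tspan31 passed. Further probe sets of Tnxb and Septin4 rose too, by 2.18 and 1.68, and so did a further probe set of Csrp1 that was under background on all 4 lung arrays.

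The 12 largest decreases in tips were led by Stxbp3, a syntaxin-binding protein of vesicle fusion, which fell from a signal of 18860 ± 3446 in lung to 668 ± 428 in tips, a log2 difference of -4.78 ± 0.42. Gnai3, the alpha subunit of an inhibitory G protein, gave -4.51 ± 0.37, the ubiquitin ligase gene Rnf13 -4.45 ± 0.40 and Sypl, a relative of synaptophysin, -4.35 ± 0.35. Dr1, Sec23ip and Zfp281 were under background on all 4 tip arrays, and lung was at least 7.76-fold, 6.30-fold and 5.38-fold brighter. The others, Marcks, Dnajb6, Rcn2, Usp33 and Hnrnpll, differed by -3.96, -3.88, -3.83, -3.73 and -3.73. Of the 4 tip arrays, Usp33 was under background on 3 and Stxbp3, Marcks and Dnajb6 on 2. Gnai3, Rnf13, Rcn2 and Hnrnpll were under it on 1. A further probe set of Dnajb6 differed by 1.36 ± 0.37 the other way (adjusted p = 0.0272). These 24 genes had adjusted p between 0.000941 and 0.00641.

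Over all 5642 genes, on the brightest probe set of each, 826 rose and 851 fell, and the counts of each list below are to be read against this share. The 5 scalings named below are the trimmed mean used here, quantile normalization, median centring, cyclic loess and no rescaling. No rescaling kept 2105 of the 2106 calls, as the deposited values were already at a common level. Holding under all 5 is thus tested by quantile normalization, median centring and cyclic loess alone. Matrix genes, like all genes, differed in both directions. Of 12 elastic fibre genes tested, 3 rose and 0 fell: Ltbp2 by 1.76 ± 0.45, Fbln2 by 1.58 ± 0.32 and Mfap4 by 1.54 ± 0.43. Adjusted over the list alone, 3 rose and 1 fell, and 0 of the increases held under all 5 scalings. With quantile normalization 2 rose and 1 fell, with median centring 0 and 2, and with cyclic loess 3 and 1. Eln, the elastin gene, had a signal of 100430 ± 69398 in tips and 55840 ± 24315 in lung, a log2 difference of 0.72 ± 0.58 (adjusted p = 0.356), and a further probe set 1.04 ± 0.58 (0.196). The lysyl oxidase gene Lox gave -1.67 ± 0.57 (adjusted p = 0.0542, and 0.00839 with the experiment as a block, where 2452 probe sets passed in all) and 0.71 at another probe set, and Mfap4 -0.06 at another. Of 16 collagen and matrix genes, 2 rose and 3 fell, or 3 and 3 adjusted over the list alone. The counts were 4 and 1 with quantile normalization, 1 and 4 with median centring and 5 and 1 with cyclic loess. Tnc, which encodes tenascin-C, rose by 1.90 ± 0.36 and the proteoglycan gene Bgn by 1.43 ± 0.32. Col5a2, Col6a3 and Col5a1 fell by 2.02, 1.57 and 1.07, and of the list Tnc and Col5a2 held under all 5 scalings. Ltbp2, Mfap4 and Col5a1 did not pass with the common floor, and with the lower floor of 792 Ltbp2 and Col5a1 passed. Other probe sets of Tnc and Bgn gave 0.93 (adjusted p = 0.0685) and 0.51 (0.199). Of 14 basement membrane genes, 3 rose and 0 fell, also when adjusted over the list alone. These were Lamb2 by 2.20 ± 0.41, the perlecan gene Hspg2 by 1.76 ± 0.31 and Lama4 by 1.25 ± 0.34, of which Lamb2 and Hspg2 held under all 5 scalings.

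Of 12 genes of the contractile apparatus of myofibroblasts and smooth muscle, 6 rose and 1 fell, or 6 and 2 adjusted over the list alone. Csrp1 rose by 3.13 ± 0.37, Tagln (transgelin, an actin-binding protein) by 1.97 ± 0.35 and the actin gene Actg2 by 1.59 ± 0.28, and these held under all 5 scalings. Myh11, Myl9 and Des rose by 1.32, 1.22 and 1.10. The myosin light chain kinase gene Mylk fell by 2.50 ± 0.44, under all 5 scalings as well. Acta2, the alpha-smooth muscle actin gene used as a myofibroblast marker, had a signal of 17743 ± 3373 in tips and 17565 ± 10339 in lung, a log2 difference of 0.09 ± 0.42 (adjusted p = 0.890) whose sign changed under 4 of 19 alternatives. Of 18 genes of the actin cytoskeleton and migration, 6 rose and 2 fell, with the same counts adjusted over the list alone. The non-muscle myosin gene Myh9 rose by 2.21 ± 0.29, Cnn2 by 1.83 ± 0.37 and Tmsb4x by 1.51 ± 0.30, while the annexin gene Anxa1 fell by 2.64 ± 0.36. Myh9, Cnn2 and Anxa1 held under all 5 scalings, but Cnn2 did not pass with the common floor (1.11), nor did Des, and with the lower floor of 792 both passed. Other probe sets of Anxa1 gave -2.27 and -0.41.

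Of 13 alveolar fibroblast genes, 2 rose and 3 fell, or 3 and 3 adjusted over the list alone. Meox2 fell by 3.16 ± 0.42 and the lipoprotein lipase gene Lpl by 2.48 ± 0.34, both under all 5 scalings, and Limch1 by 1.38 ± 0.34. Mfap4 and Tgfbi rose by 1.54 and 1.07. Limch1, Mfap4 and Tgfbi did not pass with the common floor, and with the lower floor of 792 Limch1 passed. A further probe set of Lpl gave -0.38 (adjusted p = 0.532) and of Limch1 -0.82 (0.286). Pdgfra, the receptor that marks myofibroblast precursors, gave -0.83 ± 0.33 (adjusted p = 0.0861) and 0.38 at another probe set. Of 6 pericyte genes, 0 passed, with limma over all genes and adjusted over the list alone. At an unadjusted p under 0.05 there was 1, Notch3, which differed by 0.79 ± 0.32 (adjusted p = 0.0931).

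**Figure D2:**
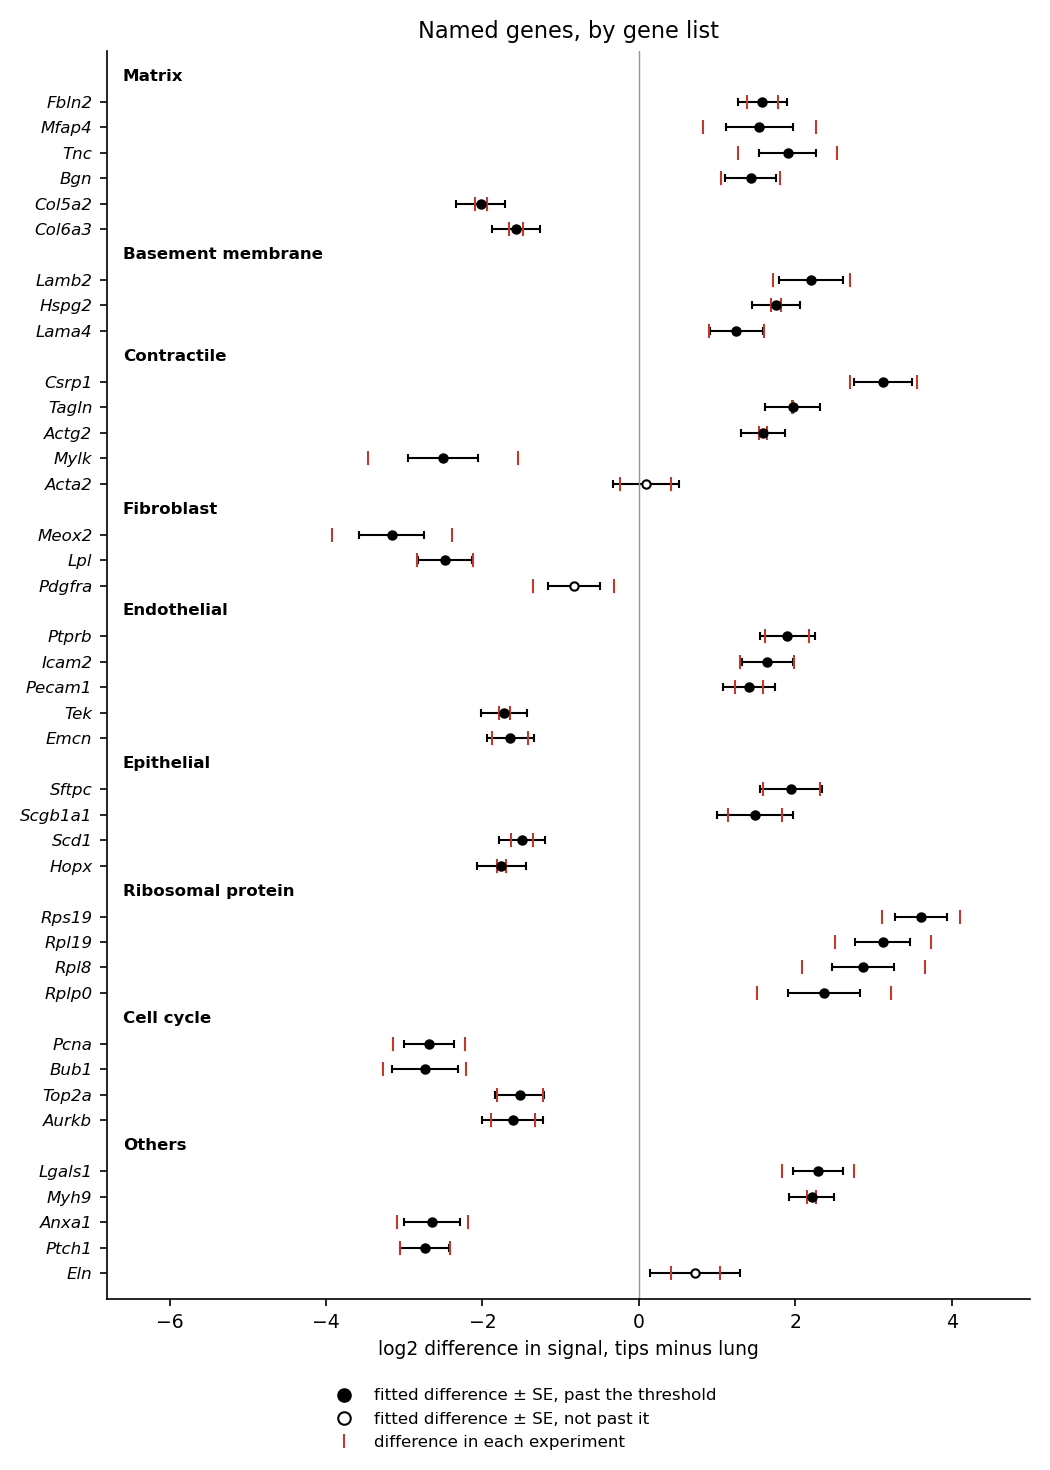
Log2 difference of tips minus lung for named genes, grouped by list on the vertical axis. Circles are fitted differences with their standard error, n = 2 RNA samples per group, filled where past the threshold, and red bars are the differences in experiments 1 and 2. Open circles are genes not past it, here Eln, Acta2 and Pdgfra. Among the endothelial genes, Ptprb, Icam2 and Pecam1 lie to the right of 0 and Tek and Emcn to the left.

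Of 18 endothelial genes, 6 rose and 2 fell, or 7 and 2 adjusted over the list alone. The receptor genes Eng, Tie1 and Ptprb rose by 1.99, 1.94 and 1.90, and Icam2, Pecam1 and the tight junction gene Cldn5 by 1.64, 1.41 and 1.20. The angiopoietin receptor gene Tek fell by 1.72 ± 0.29 and the sialomucin gene Emcn by 1.64 ± 0.30. Tie1, Ptprb, Icam2, Tek and Emcn held under all 5 scalings, and Eng, Pecam1 and Cldn5 did not. With the common floor Tie1, Eng and Cldn5 did not pass, and with the lower floor of 792 Tie1 and Eng did. Of 6 genes of large vessel endothelium, 0 rose and 3 fell, also when adjusted over the list alone: Vcam1 by 2.38 ± 0.32, the ephrin gene Efnb2 by 1.74 ± 0.41 and Nr2f2 by 1.19 ± 0.37. Of these Efnb2 and Nr2f2 did not pass with the common floor, Efnb2 passed with the lower floor, and Nr2f2 passed under 10 of 19 alternatives. A further probe set of Vcam1 gave 1.30 ± 0.44 (adjusted p = 0.0533, and 0.0410 with the experiment as a block, where 2452 probe sets passed).

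Epithelial marker genes also went both ways. Of 11 genes of alveolar type II cells, 3 rose and 1 fell, also when adjusted over the list alone. Sftpc, the gene of surfactant protein C, rose from a signal of 27130 ± 8140 in lung to 102540 ± 5425 in tips (SD, n = 2), a log2 difference of 1.95 ± 0.40 (limma adjusted p = 0.00856), and held under all 5 scalings. Muc1 and the fatty acid synthase gene Fasn rose by 0.95 and 0.92, and the desaturase gene Scd1 fell by 1.49 ± 0.29, with -0.59 and 0.03 at other probe sets (adjusted p = 0.346 and 0.972). Of 7 genes of alveolar type I cells, 1 rose and 1 fell, or 4 and 2 adjusted over the list alone. Vegfa, the vascular growth factor gene, rose by 1.58 ± 0.39 and Hopx fell by 1.76 ± 0.31, of which Hopx held under all 5 scalings. Of 8 genes of airway secretory cells, 1 rose and 1 fell, and 0 and 0 adjusted over the list alone. Scgb1a1, the secretoglobin of club cells, rose from 17323 ± 5712 to 53091 ± 33255, by 1.49 ± 0.48 (limma adjusted p = 0.0479), and Aldh1a1 fell by 1.51 ± 0.44, with 0.84 at another probe set (adjusted p = 0.128). Of the genes named in this paragraph Muc1, Fasn, Vegfa, Scgb1a1 and Aldh1a1 did not pass with the common floor, and with the lower floor of 792 Vegfa passed. Scgb1a1, Fasn, Muc1 and Aldh1a1 passed under 9, 9, 8 and 10 of 19 alternatives, and Vegfa under 10 of 18.

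Ribosomal proteins were the only list past the threshold of camera. Of 23 genes tested, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone, and the mean log2 difference was 1.26 (camera adjusted p = 0.00361). The call was lost with an estimated correlation between genes (adjusted p = 0.829). Rps19, Rpl19, Rpl8 and Rplp0 rose by 3.61, 3.12, 2.87 and 2.37, and together with Rpl41, at 2.31, they held under all 5 scalings, but Rplp0 did not pass with the common floor, though it did with the lower floor of 792. A further probe set of Rpl19 gave 1.30 (adjusted p = 0.102, and 0.0150 with the experiment as a block, where 2452 probe sets passed). Of 30 genes of oxidative phosphorylation, 9 rose and 6 fell, or 11 and 7 adjusted over the list alone. The counts were 6 and 2 of 29 with quantile normalization, 3 and 9 with median centring and 7 and 2 with cyclic loess. Genes of ATP synthase stood on both sides: Atp5d rose by 2.12 ± 0.32 and Atp5c1 fell by 2.13 ± 0.30, and further probe sets of each passed in the same direction. Cox5b, of cytochrome c oxidase, rose by 2.28 ± 0.36 and Uqcrb, of complex III, fell by 1.78 ± 0.31, and these 4 genes held under all 5 scalings, but Cox5b did not pass with the common floor (1.03), though it did with the lower floor.

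Of 21 cell cycle genes, 2 rose and 5 fell, also when adjusted over the list alone. Pcna, the sliding clamp of DNA replication, fell by 2.68 ± 0.32, the topoisomerase gene Top2a by 1.52 ± 0.32 and the mitotic kinase gene Aurkb by 1.61 ± 0.39. Bub1 was under background on all 4 tip arrays, and lung was at least 3.39-fold brighter. These and Plk1, which fell by 1.28, held under all 5 scalings, while the increases of Mcm7 and Mcm2, by 1.41 and 1.20, did not. With the common floor Aurkb (-0.45), Plk1, Mcm7 and Mcm2 did not pass, and with the lower floor of 792 all but Mcm7 did. Of 20 signalling genes of septation, 2 rose and 3 fell, or 2 and 2 adjusted over the list alone. The counts were 0 and 1 with quantile normalization, 0 and 6 with median centring and 1 and 2 with cyclic loess. Ptch1 fell by 2.74 ± 0.31, under all 5 scalings, with 1.23 ± 0.41 at another probe set (adjusted p = 0.0521, and 0.0349 with the block). The growth factor gene Fgf18 rose by 1.80 ± 0.47 and Vegfa by 1.58 ± 0.39, and Efnb2 and Notch1 fell by 1.74 and 0.94, and these 4 did not pass with the common floor, though Vegfa and Efnb2 did with the lower floor. Of 5 galectin genes, Lgals1 passed, in both adjustments, and Lgals3, Lgals4 and Lgals2 gave 1.38, 1.02 and 0.97 without passing, though with the experiment as a block, which gave 2452 probe sets, Lgals3 had an adjusted p of 0.0492.

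Over all probe sets tested the median log2 difference was 0.35, and relative to it Lgals1 differed by 1.94, Sftpc by 1.60, Pecam1 by 1.06, Scgb1a1 by 1.14, Ptch1 by -3.09 and Pcna by -3.03. With quantile normalization the median was 0.03 and the calls were 608 higher and 1020 lower, with median centring -0.19 and 271 and 1512, and with cyclic loess 0.05 and 806 and 1156. Under all 5 scalings 267 probe sets stayed higher and 853 stayed lower. With 1 RNA sample left out, the spread comes from the other group alone. Without the lung RNA of experiment 1, 349 probe sets and 39 of the 99 named genes past the threshold passed, and without that of experiment 2, 556 and 53. Without the tip RNA of experiment 2, 3324 passed.

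The tip-to-lung differences of the experiments correlated with a Pearson r of 0.738 and a Spearman rho of 0.681 across probe sets, which are not independent replicates. The sign was the same for 78.8% of all tested probe sets. It was the same for 100% of those called, but these were selected on the same experiments, which largely fixes that share. Arrays of the same RNA differed more between tips than between lungs. The SD of their log2 difference was 0.58 and 0.53 for the lung RNAs and 0.99 and 0.72 for the tip RNAs of experiments 1 and 2. Between the RNA samples of a group it was 0.50 for lung and 0.79 for tips, and between tips and lung it was 1.35 and 1.10. These values are from means of 2 arrays, which lowers them against those of single arrays, so the 2 kinds are not directly comparable.

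As a sign of RNA quality, signals along the control transcripts were compared by exact 2-sided permutation tests, which with 2 against 2 RNA samples cannot go below p = 0.333. The 3' over 5' ratio of beta-actin was 5.90 ± 0.80 in lung and 5.94 ± 0.17 in tips on the log2 scale (SD, n = 2, exact p = 1). That of GAPDH was 1.71 ± 0.86 in lung and 2.95 ± 0.61 in tips (exact p = 0.333). The 3' over middle ratio of beta-actin was 4.37 ± 0.25 in lung and 3.47 ± 0.08 in tips, and that of GAPDH -0.16 ± 0.20 and 1.09 ± 0.13 (exact p = 0.333 for each). The bacterial and yeast control probe sets differed by 0.61 on the log2 scale, and 0 of 19 passed limma's adjusted threshold, with 1 at an unadjusted p under 0.05.

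**Figure D3:**
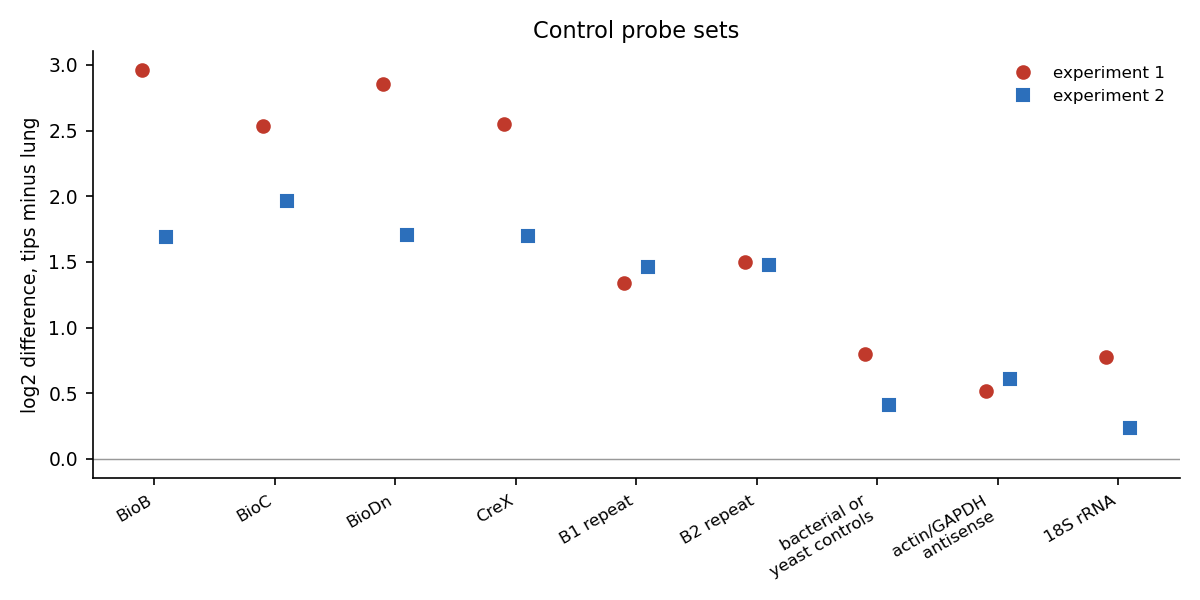
Log2 difference of tips minus lung for groups of control probe sets, with experiment 1 as circles and experiment 2 as squares. BioB, BioC, BioDn and CreX are transcripts added at hybridisation and lie between 1.69 and 2.96, the B1 and B2 repeats lie closer together at 1.34 and above, and the others between 0.24 and 0.80.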

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

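The tests of explanations in this part and the common floors were chosen after the result was seen, and the scalings were chosen before. Control probe sets were left out of the fit of the 7453 probe sets between tips and lung. The signal of 6 kinds differed between the arrays of the groups by more than the mean of the bacterial and yeast control probe sets for absent transcripts. That mean was 0.61 on the log2 scale with the offset, but single absent controls reached 1.64, above both repeats. Without the offset the absent controls were brighter on tip arrays by 3.14-fold and 1.88-fold in experiments 1 and 2. The transcripts added at hybridisation were brighter on tip arrays by 2.33 (BioB), 2.25 (BioC), 2.28 (BioDn) and 2.12 (CreX). They do not come from the tissue, and the median of the probe sets called higher was 1.52 and Lgals1 differed by 2.29. The higher calls thus hold relative to the signal of the whole array. Relative to the added transcripts, a call of median size or that of Lgals1 does not stand higher. Larger differences, such as those of Rps19 (3.61) and Rpl19 (3.12), exceeded those of the added transcripts. The probe sets for the B1 and B2 repeats, short interspersed elements of the mouse genome, were brighter by 1.40 and 1.49. Each of the 6 kinds has an exact permutation p of 0.333, the smallest that 2 against 2 RNA samples can give.

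The B1 and B2 repeats were brighter in tips by 2.55-fold and 2.76-fold (B1) and 2.83-fold and 2.78-fold (B2) in experiments 1 and 2, though single arrays of experiment 1 gave 3.39-fold and 2.37-fold for B2. Raised background is argued against, since the smaller of the rises in signal was 78210 and the largest of an absent control was 750. Against a larger scaling factor on the tip arrays speaks the ratio of the experiment 1 fold to that of experiment 2, 0.92 for B1 and 1.02 for B2 but 1.47 to 2.39 for the added transcripts. Over the choices of 1 array per RNA it reached at most 1.16 for B1 and 1.40 for B2 and was lowest at 1.97, 1.76 and 1.56 for BioB, BioDn and CreX, but it went down to 1.09 for BioC, and these choices show the spread between arrays and not that between RNA samples, so scaling stays open. Scaling, unspliced RNA or genomic DNA in the captured tissue and a difference between the tissues in transcribed repeats cannot be told apart, since the antisense actin and GAPDH controls differed by 0.56, within the range of the absent controls, up to 1.64.

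The probe sets called higher in tips were weighed against the background and the scaling of the arrays. Raised background is argued against as the whole cause of the 1084 higher calls, since 275 remained past the threshold with the common floor of 1244, against the 5% allowed as false calls. With the lower floor of 792, 720 remained, but the array with the background of 1244 stays in that fit, so this count does not bear on background. For the 809 that did not remain with the floor of 1244, the median fell from 1.50 ± 0.40 to 0.79 ± 0.23 (median standard error) as values under the floor were set to it. For these, background and a tissue difference cannot be told apart. All 5 scalings leave the arrays at a common level and make no use of the added transcripts. They cannot test a larger scaling factor on the tip arrays, where the added transcripts were brighter by 2.12 to 2.33. The choice among these scalings is argued against as the whole cause, since 267 calls held under all 5. Of these, quantile normalization, median centring and cyclic loess are the test, while no rescaling nearly repeats the fit and ended 1 higher call. For the other 817, with a median of 1.40 ± 0.37 before and 1.14 ± 0.38 after quantile normalization, which ended 565 calls as cyclic loess ended 444, scaling and a difference in the amount of RNA between the tissues cannot be told apart, and for 251 of them the call ended only with median centring, which by construction lowers every difference alike.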

How the results depend on the processing

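The common floors were chosen after the data were seen, and the other alternatives before. No probe set called here was called in the opposite direction under any alternative. Of the 99 named genes past the threshold 34, Lgals1 among them, passed under all 19 alternatives run on named genes. The probe sets higher in tips numbered 608 with quantile normalization and 271 with median centring, and 533 with array 1 of each RNA (1263 in all) and 686 with array 2. With the common floor 860 passed, 275 higher and 585 lower, since differences under the floor are removed. Array 2 of the tip RNA of experiment 1 alone sets that floor of 1244; with the next highest level, 792, 1617 passed, 786 higher and 831 lower, and 81 of the 99 named genes remained. Leaving out an RNA sample leaves 1 in its group, so that the spread comes from the other group alone, and gave totals of 349 to 3324, with 72 to 1866 higher and 277 to 1458 lower, lowest without the lung RNA of experiment 1 and highest without the tip RNA of experiment 2. With the experiment as a replicate block 2452 passed, 11 more named genes among them, and it ended no call of a named gene or list. The 11 were Lox, Col4a2, Emp2, Rsph1, Krt8, Mpeg1, Lgals3, Ckm, Col9a1, Gap43 and Klf4. The ribosomal list was the 1 list past the threshold; 0 passed with camera and an estimated correlation and 0 with directional fry, and 27 with mixed fry, which asks for change in either direction. The correlation between experiments was 0.70 with quantile normalization, 0.72 with cyclic loess, 0.70 with no offset, 0.76 with the doubled offset, 0.64 without a filter, 0.81 with the filter at the 60th percentile, 0.63 with array 1 and 0.65 with array 2, each with the filter set anew, and 0.82 with the floor. The 3' to 5' difference of beta-actin was 0.96 with quantile normalization, 0.70 with array 1 and -0.63 with array 2, and that of GAPDH 2.04 with quantile normalization. Except where the alternative leaves out data or removes differences, the cause was not tested. Signal over background is the limit for dim genes: 159 calls had every array of the dimmer group under background.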

Other observations

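Of the tests in this part, those on probe sets of the same gene were chosen after the result was seen, except that on dim or cross-hybridising probe sets. Marker genes of blood and immune cells, differences as log2 of tips minus lung with n = 2 RNA samples per group, went both ways. Of 15 macrophage genes 0 rose and 2 fell, or 0 and 1 adjusted over the list alone: Ctss, a lysosomal protease gene, by 3.05 ± 0.31 and the mannose receptor gene Mrc1 by 1.62 ± 0.51, under all 5 scalings, though Mrc1 passed under 10 of 18 alternatives and not with either common floor. Of 9 neutrophil genes S100a9 and Chil1 rose, by 1.69 and 1.00, or 1 and 0 adjusted over the list alone. Of 8 lymphocyte genes 3 rose and 1 fell, in both adjustments: Cd79b, Ighm and Cd4 rose and the pan-leukocyte gene Ptprc fell by 1.95 ± 0.41, the only one that held under all 5 scalings. With the common floor these neutrophil and lymphocyte genes and Hbb-b2 did not pass, and with the lower floor of 792 all of them but Chil1 and Cd4 did. Cd4 was under background on all lung arrays. Of 9 erythroid genes 4 rose and 2 fell, in both adjustments: Hbb-b2 rose by 1.36 ± 0.35 and the carbonic anhydrase gene Car2 fell by 1.51 ± 0.33, and 0 held under all 5 scalings. Of 4 mast cell and platelet genes 0 passed limma in either adjustment, with 1 (Gp1bb, 1.10) at an unadjusted p under 0.05.

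Of 6 ciliated cell genes Foxj1 rose by 1.68 ± 0.42 and Cd24a fell by 1.37 ± 0.41, in both adjustments. Of 7 keratin and basal cell genes Krt19 rose, in both adjustments, and was at least 2.14-fold over the background of each lung array, where lung lay under it. With the common floor it differed by 0.16 and did not pass. Of 3 mesothelial genes Rarres2 rose by 1.66 ± 0.33, under all 5 scalings, and Krt19 rose but not under all 5, with 2 rising and 1 falling adjusted over the list alone. Of 5 cartilage genes Matn4 and Col9a3 rose by 2.13 and 1.32, or 3 and 0 adjusted over the list alone. Of 8 muscle genes Myl4 rose by 1.05, which passed under 9 of 19 alternatives, and 0 adjusted over the list alone. Of 7 nerve genes 0 passed limma in either adjustment, with 3 at an unadjusted p under 0.05, and of Tubb3 (1.19) another probe set fell, under background on all tip arrays. With the experiment as a block, Gap43 (-1.37) had a limma adjusted p of 0.0299. Of 4 adipose and thymus genes Rag1 rose by 2.09 ± 0.50 and Cd1d1 fell by 1.79 ± 0.34, in both adjustments. Of 6 retinoid genes Dhrs3 and Rxrb rose by 1.71 and 1.31 and Aldh1a1 fell by 1.51, with 0.84 at another probe set, in both adjustments. Of 17 immediate early and stress genes Ier2 rose by 0.92 and Hspa1b and Fos fell, Fos by 1.42 ± 0.43, or 0 and 1 adjusted over the list alone. Of the called list members in this paragraph Rarres2, Col9a3 and Cd1d1 passed with the common floor and the others did not, and with the lower floor of 792 Foxj1, Hspa1b, Ier2, Myl4 and Rag1 passed as well.

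Probe sets of the same gene often differed unlike each other between tips and lung, as Ptch1 does with -2.74 and 1.23, and 13 of 896 genes had probe sets called in opposite directions. Random measurement error is argued against: the differences in experiments 1 and 2 correlated at 0.731 for the same probe set and at 0.326 for another of its gene, a gap of 0.404 (95% bootstrap interval 0.358 to 0.455). Dim probe sets, or those whose suffix marks shared probes, are argued against as the whole cause. Over bright probe sets with the plain suffix, the correlation with another probe set was 37.8% of that with itself. The interval was 20.9 to 53.3, where at least 80% was predicted. Brightness was the mean over all arrays, so probe sets dim in 1 tissue and cross-hybridisation that no suffix marks were not tested. A property of the stretch of transcript that a probe set reads, for which distance to the 3' end after amplification is a candidate explanation, stays open beside a tissue difference in gene level. The 0.326 lies above the highest of 200 draws from different genes at the same level, 0.0704, which the latter needs, but an effect of amplification on the whole transcript would raise it too and was not tested.

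The 4 RNA samples make 3 splits into 2 and 2, too few for a share under 0.05. The real split gave 2106 probe sets past the threshold and 1 of the 3 splits gave as many, the real split itself, while the highest of the others gave 0 with limma (8 and 4 at an unadjusted p under 0.05).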
